A study of Mus musculus with 2 samples.

How the data were processed

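Small RNA libraries (microRNA-seq) were made from mouse neural tube at embryonic day 13.5. Per the labels, both libraries come from pooled male and female embryos of the strain B6NCrl and are numbered as biological replicates 1 and 2, with separate tissue samples and 1 shared strain-level donor entry. The labels give 1 condition only, so all comparisons are within or between these 2 libraries.

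The deposited values are raw counts per miRNA gene, on genome build mm10 with the gene annotation M4, per the file headers. The aligner and its version are not given in the sources used here. Each deposited table holds 3 count columns for 1973 annotated genes, preceded by 4 lines with the reads that were unmapped, mapped to several places, in no gene, or ambiguous. All 3 columns add up to the same total in each library, 13739569 reads in replicate 1 and 10685196 in replicate 2. This layout, with multimapping reads kept out of every gene, was inferred from the values. Multimapping reads made up 28.5% and 31.0% of the reads, unmapped reads 17.4% and 12.2%, and reads in no gene 2.95% and 3.10% of the same-strand column. These classes were left out of all totals. Reads of miRNAs with several genomic copies may be among the multimapping reads, and how many was not measured here.

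The second count column was used as the same-strand count: it held 7019469 counts in replicate 1 and 5738209 in replicate 2, against 100058 and 85834 in the opposite-strand column. CPM (counts scaled to the same-strand total of the library) and shares were computed here from the same-strand totals. Gene names, coordinates and host genes were taken from GENCODE M21, on GRCm38, the assembly also called mm10. The gene identifiers were matched without their version, and 1894 of 1973 matched. The 79 unmatched genes held 8 counts in both libraries together. Coordinates are those of M21 and were not compared with the M4 annotation, which was not used here. Hairpin sequences of M21 were searched for stretches of 20 nt shared with another miRNA gene at a different place. This marks 929 genes of the table as open to lost reads, but misses copies that differ by single bases.

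The comparisons, gene lists and rule for named genes were fixed before the data were examined. The central 95% used as the limit for list differences, the exact intervals of replicate ratios, and the search for shared stretches were added afterwards. They were 18 lists of miRNA genes, 6 ratios between lists or genes, and a rule for named genes. The rule took the 20 genes of highest mean CPM, up to 3 members of each list with the highest mean CPM, the 3 highest and 3 lowest replicate differences among genes with at least 100 counts summed, and both genes of the Mir10 pair. Errors are given as the SD of the 2 libraries. The 2 libraries were compared by a chi-square test of the counts, meant to ask whether they could be 1 library deposited in duplicate. Since their totals differ, it can only show whether they differ by more than counting error. The biological coefficient of variation came from an intercept-only common dispersion in edgeR 4.0.16 (R 4.3.3) with TMM factors, over genes with at least 10 counts in each library. Replicate differences are log2 ratios of counts with a pseudocount of 0.5, scaled by TMM. A list's median difference was ranked among 10000 random lists, each member replaced by 1 of the 50 genes nearest in mean expression. Percentiles describe these libraries and are not tests between conditions. Other steps used Python 3.11.15 with scipy 1.17.1.

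Wilson 95% intervals of shares and exact 95% intervals of ratios cover counting error only, and reads without molecular identifiers are not independent molecules. The procedures were tested on simulated data. A pair of simulated libraries without added variation gave a chi-square of 0.98 per degree of freedom over 374 genes. With a simulated coefficient of variation of 0.2, 0.209 was recovered over 382 genes. For 200 genes changed by 1 log2 unit either way on that background, the median estimates were 0.94 and -0.95. In 100 simulations of unchanged libraries over 455 genes, 5.78% of list medians fell outside the central 95% of random lists, and a mesenchymal list raised by 1 log2 unit was recovered in 100% of them. That change is larger than the list medians found outside the central 95% in the real libraries (0.33 to 0.61, and -0.52). Recovery of changes of that size was not simulated. These simulations drew genes independently and hold no shared transcripts. The alternatives tried were other count minimums, the unstranded column, summed or single copies, the most abundant gene left out, DESeq2 1.42.0 size factors or total counts, other pseudocounts, and each replicate left out.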

Results

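MicroRNA abundance was measured in the neural tube of mouse embryos at day 13.5, the embryonic tissue that forms the brain and spinal cord. The data describe 1 condition in 2 biological replicates, with 7019469 and 5738209 same-strand counts on miRNA genes. There was no second condition, so the comparisons ask which miRNAs dominate the libraries, how groups of miRNAs with known cell types compare in abundance, and how far the 2 libraries differ. With 2 replicates, an exact two-sided sign-flip test cannot give a p-value below 0.5, and differences are therefore set against the spread of the replicates.

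The counts on miRNA genes were dominated by a few genes. Mir10a made up 20.5% ± 1.08 (SD, n = 2) of the counts, Mir10b 15.5% ± 1.81 and Mir99a 12.2% ± 0.13. These 3 genes together held 48.1% ± 0.60 of the counts, and the 10 most abundant held 65.4% ± 0.54 (65.1% and 65.8% in the replicates). The other 7 of these 10 were Mir100, Mirlet7g, Mir335, Mirlet7i, Mir17, Mir130a and Mir99b, at means from 39109 CPM for Mir100 down to 16695 CPM for Mir99b. Mir335, in an intron of the imprinted gene Mest, reached 26174 ± 3152 CPM. Ranks 11 to 20 were held by Mir126a, Mir487b, Mir30e, Mir182, Mir183, Mir26b, Mir23b, Mir181c, Mir93 and Mir149, the last at 9145 ± 1123 CPM. Of the 1973 genes, 371 had at least 10 counts in each library, 273 had at least 100, and 1247 had none in either. Of the 20 most abundant genes, 15 lie within an annotated gene on the same strand and 18 share no stretch of 20 nt with another miRNA hairpin. Multimapping reads, 28.5% and 31.0% of the reads, were inferred to be in no gene's count. The ranks and shares therefore cover counted reads only, and miRNAs with several copies may rank too low. Loss of such reads may itself keep genes that share a stretch out of the top 20.

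The miRNAs encoded inside the Hox clusters, which pattern the body along its long axis, were the most abundant of the 18 lists, at 37.6% ± 0.76 of all counts. This rank rested on Mir10a: without it in the list and the total, the share was 21.6%, below the miR-125/99/100 list at 22.9%. Mir99a, the largest member of the miR-125/99/100 list at 12.2% of the counts, was kept. The 2 lists were thus not treated alike, and the reversal does not show which rank is the more fragile. All 6 members of the Hox cluster list had at least 10 counts in each library. Mir10a (chromosome 11, 96317165 to 96317274, plus strand, GRCm38) lies between Hoxb5 and Hoxb4, outside annotated genes of its strand. Mir10b (chromosome 2, 74726070 to 74726137, plus strand) lies in introns of Hoxd3 and Hoxd4. Mir10a was the higher of the pair in both replicates. The log2 ratio of Mir10b to Mir10a was -0.23 in replicate 1 and -0.58 in replicate 2, a mean of -0.40 ± 0.24, or 1.32-fold in favour of Mir10a. The mature sequences of this pair are nearly identical, so reads with errors could be counted on either. Mir615, in an intron of Hoxc5 (chromosome 15, 103014910 to 103015001), reached 8833 ± 873 CPM. Mir196b, in an exon of Hoxa9, was at 6322 ± 733 CPM, and Mir196a-2, in an intron of Hoxc5, at 1302 ± 192 CPM. Mir196a-1 was at 23.8 ± 0.39 CPM. Both Mir196a copies share a stretch of 20 nt, so reads from the shared part may be missing from their counts. Mir196a-1, Mir196a-2 and Mir196b were named after their values were seen.

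**Figure D1:**
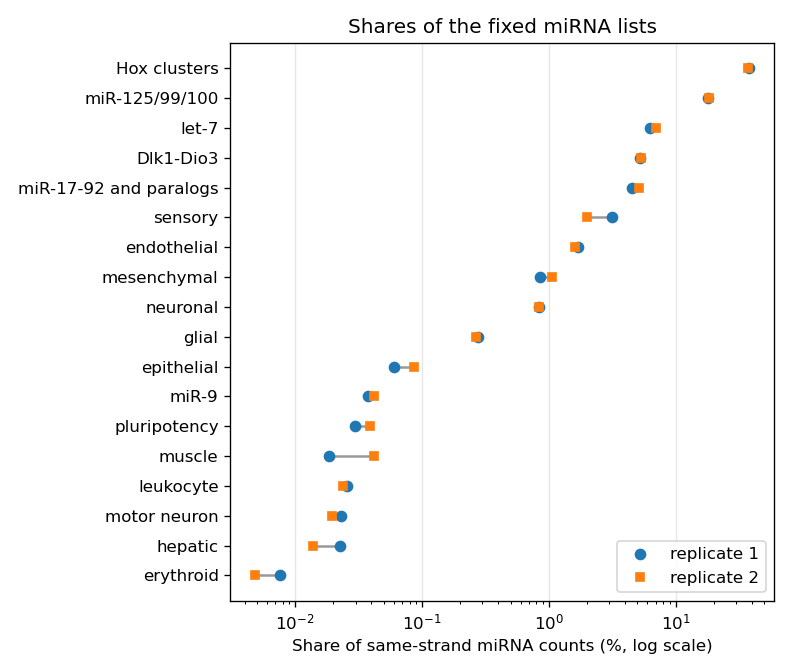
Share of same-strand miRNA counts (percent, log axis) of each of the 18 fixed lists in replicate 1 (circles) and replicate 2 (squares), with a line joining the 2 libraries. The Hox cluster list is highest at 37.6% on average and the erythroid list lowest at 0.00622%. The muscle list, most of whose counts are from Mir206, shows the widest gap, from 0.0183% to 0.0419%.

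MiRNAs of developmental timing and of proliferation were both abundant, and the timing group held the larger share of the counts. The let-7 list, a family whose mature products accumulate as tissues differentiate, held 6.64% ± 0.57 of the counts, with Mirlet7g at 29455 ± 3732 CPM and Mirlet7i at 25538 ± 1633 CPM, then Mirlet7b at 4445 ± 50.2 CPM. The miR-17-92 list and its paralogs, which promote proliferation, held 4.84% ± 0.41, led by Mir17 at 19154 ± 661, Mir93 at 9294 ± 850 and Mir20a at 8098 ± 1408 CPM. The let-7 list exceeded the miR-17-92 list by a log2 ratio of 0.46 ± 0.0025, or 1.37-fold, a difference larger than the SD of the 2 ratios. Both shares were higher in replicate 2 (let-7 6.24% and 7.05%, miR-17-92 4.56% and 5.13%), which keeps this SD small. With 2 values, the SD is a poor guide to the precision of the ratio. This ratio compares counts, not molecules, since ligation efficiency differs between miRNAs. Reads may also be missing on both sides, as 5 of the 10 let-7 genes and 4 of the 15 miR-17-92 genes share sequence with another copy. How such reads would move the ratio was not measured. The miR-125/99/100 list, whose genes lie in clusters with let-7 genes, held 18.2% ± 0.16, of which Mir99a (121726 ± 1320 CPM), Mir100 (39109 ± 1210) and Mir99b (16695 ± 444) were the main part. Mature sequences are similar among let-7 members, between Mir99a and Mir100, and among Mir17, Mir20a and Mir93, so the split of reads between these genes is uncertain.

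The neuronal list held a smaller part of the counts, 0.839% ± 0.0093, with 14 of its 16 members above 10 counts in each library. Mir137, on chromosome 3 (118433857 to 118433929) and without a 20-nt stretch shared with another miRNA gene, led at 5096 ± 101 CPM, ahead of Mir138-1 at 649 ± 156 and Mir153 at 508 ± 0.78 CPM. The glial list, miRNAs of oligodendrocyte differentiation, held 0.273% ± 0.0053, mostly from Mir219a-2 at 2351 ± 12.9 CPM, with Mir338 at 221 ± 31.0 and Mir219a-1 at 156 ± 9.16 CPM. The neuronal list was 3.08-fold higher than the glial list, a log2 ratio of 1.62 ± 0.012. The miR-9 list stood at 0.0394% ± 0.0029, almost entirely from Mir9-3 at 394 ± 29.7 CPM. Its log2 ratio to the neuronal list was -4.41 ± 0.12. The motor neuron list, the 2 Mir218 genes, held 0.0213% ± 0.0022. Mir218-2, in an intron of Slit3, was at 182 ± 12.5 CPM and Mir218-1, in an intron of Slit2, at 30.3 ± 9.88 CPM. These levels of miR-9, of miR-218 and of the neuronal list may be underestimates. Both miR-9 genes analysed here, both miR-218 genes, 2 of the 3 glial genes and 11 of the 16 neuronal genes share a stretch of at least 20 nt with another copy, and reads from it that map to several places are in no gene's count. The 3 copies of Mir124a, a hallmark neuronal miRNA named here after its values were seen, held 31 counts (Mir124a-2), 14 (Mir124a-1) and 1 (Mir124a-3) in replicate 1, and 15, 8 and 0 in replicate 2. Reads of a miRNA with 3 copies may be among the multimapping reads, so these counts do not show that it was scarce. The ratios of the neuronal list to other lists carry the same uncertainty.

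The imprinted Dlk1-Dio3 cluster on chromosome 12, whose miRNAs are expressed from the maternal chromosome, held 5.26% ± 0.085 of the counts, and 39 of its 40 listed members passed 10 counts in each library. Mir487b was the highest at 13973 ± 175 CPM (chromosome 12, 109727333 to 109727414), followed by Mir369 at 5832 ± 294 and Mir127 at 5421 ± 260 CPM.

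MiRNAs of other cell types were present at unequal levels. The endothelial miRNA Mir126a, in an exon of Egfl7 on chromosome 2 (26591357 to 26591429), made up 1.66% ± 0.079, and the mesenchymal list 0.960% ± 0.14, mainly Mir143 (5406 ± 540 CPM) and Mir140 (3011 ± 441 CPM). The sensory list, the Mir183, Mir96 and Mir182 cluster of sensory neurons and sense organs, made up 2.59% ± 0.83. Blood, liver and muscle lists were low. The erythroid list held 0.00622% ± 0.0020 (Mir451a 32.8 ± 17.5 CPM, Mir144 16.4 ± 1.77, Mir486 13.0 ± 0.37) and the leukocyte list 0.0246% ± 0.0014 (Mir223 140 ± 23.1, Mir155 81.1 ± 12, Mir150 25.2 ± 2.63). With the unstranded counts the leukocyte share was 0.0414%, since opposite-strand counts on Mir142b, a member with 0 same-strand counts named after its values were seen, are then included. The hepatic list held 0.0182% ± 0.0063 (Mir122 74.5 ± 62.0, Mir192 63.0 ± 2.08, Mir194-2 43.5 ± 3.35), the epithelial list 0.0736% ± 0.018 (Mir203 563 ± 136.5, Mir205 66.8 ± 37.6, Mir429 53.3 ± 7.13) and the pluripotency list 0.0341% ± 0.0065 (Mir302a 133 ± 31.3, Mir302d 109 ± 19.3, Mir302b 78.0 ± 10.6). The neuronal list exceeded the erythroid list 138-fold (log2 ratio 7.11 ± 0.45) and the muscle list 30.3-fold (log2 ratio 4.92 ± 0.86). In the muscle list 5 of 10 genes share sequence with another copy, among them Mir133a-1 and Mir133a-2, which had 0 counts and were named after their values were seen. The same holds for 3 of 7 mesenchymal, 2 of 4 hepatic and 4 of 12 pluripotency genes. The shares of these 4 lists may therefore be underestimates. The muscle share depended on the library, at 0.0183% in replicate 1 and 0.0419% in replicate 2. Mir206 alone held 824 of the 1288 muscle counts in replicate 1 and 2139 of the 2403 in replicate 2. The gap therefore came from this gene, and the other members together did not rise.

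The 2 libraries were not 1 table deposited in duplicate, as their different totals already show. The chi-square statistic of their counts was 201 per degree of freedom over 371 genes, against 0.98 for simulated libraries with counting error only. The libraries thus differed beyond counting error. The test cannot tell variation between the pooled embryo samples, or in their dissection, from variation in library preparation. The common biological coefficient of variation from edgeR was 17.3%. Across those 371 genes the log2 CPM values had a Pearson r of 0.994 and a Spearman rho of 0.992, which describe genes rather than independent replicates. Of 306 genes with at least 100 counts summed, 277 (90.5%) differed by less than 0.5 log2 units and 9 by more than 1.

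**Figure D2:**
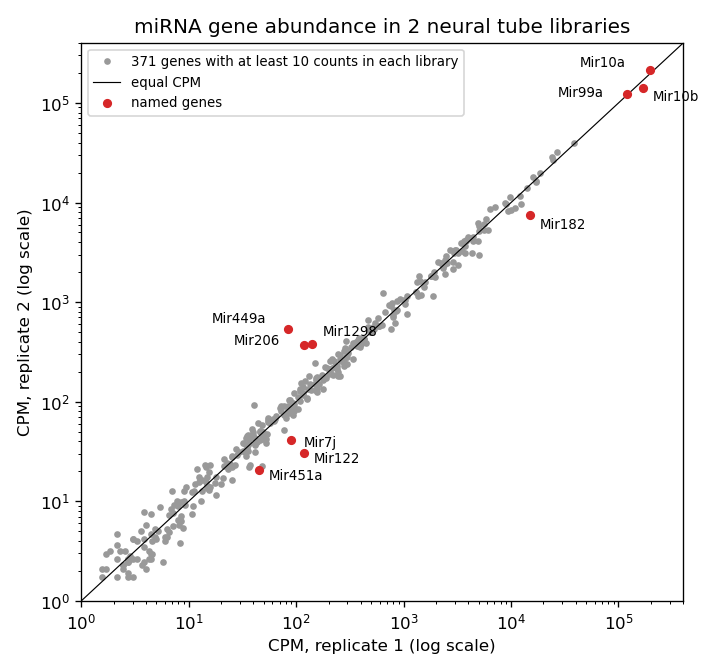
CPM of each miRNA gene in replicate 1 (x axis) and replicate 2 (y axis), both log scaled, for the 371 genes with at least 10 counts in each library, with the line of equal CPM and selected named genes in red. Mir449a, Mir206 and Mir1298 lie above the line, and Mir182, Mir122, Mir7j and Mir451a below it.

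Among the 306 genes with at least 100 counts summed, Mir449a, Mir206 and Mir1298 had the highest log2 differences and Mir122, Mir451a and Mir7j the lowest. Mir449a, a miRNA of multiciliated cells in an intron of Cdc20b (chromosome 13, 113037534 to 113037624), had 590 counts in replicate 1 and 3051 in replicate 2, a log2 difference of 2.63 (exact 95% counting interval 2.50 to 2.76). Mir206, a skeletal muscle miRNA, was higher in replicate 2 by 1.63 (1.52 to 1.75), and Mir1298, in an intron of the serotonin receptor gene Htr2c, by 1.40 (1.29 to 1.51). Mir122, the main miRNA of hepatocytes, was lower in replicate 2, with a log2 difference of -1.98 (-2.22 to -1.75). Mir451a of red cells was lower at -1.18 (-1.50 to -0.87), and Mir7j at -1.14 (-1.36 to -0.92). Other named members of the hepatic and erythroid lists differed less. Mir192 was at 0.034 (-0.17 to 0.24) and Mir194-2 at -0.19 (-0.44 to 0.06). Mir144 was at -0.25 (-0.67 to 0.15) and Mir486 at -0.09 (-0.55 to 0.37). The intervals cover counting error, and with 1 library on each side the differences have no replicate check.

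By list, the median differences of 4 of the 18 lists lay outside the central 95% of matched random lists, where 0.9 would be outside by chance if members varied independently. The random lists ignore shared transcripts, while all 3 sensory, all 7 pluripotency, 4 of 7 mesenchymal and 2 of 6 muscle members lie within 10 kb of another member on the same strand. The chance number and the percentiles do not account for this. The central 95% was chosen as the limit only after the values were seen. The sensory list was lower in replicate 2, with a median log2 difference of -0.52 (percentile 0.305), and all 3 members lower: Mir182 at -1.05, Mir96 at -0.52 and Mir183 at -0.41. The muscle list was higher in replicate 2 at a median of 0.61 (percentile 99.9), with 4 of 6 members higher and the cardiac and slow-muscle miRNA Mir208b lower at -1.12. The higher members included Mir206 at 1.63 and Mir499 at 0.83, the latter with only 49 and 73 counts. With the unstranded counts the muscle median was 0.30 with 3 of 6 members higher, at percentile 96.1 and so inside the central 95%. The mesenchymal list was higher at 0.33 (percentile 99.9; 6 of 7 members), including Mir214 at 0.91, Mir140 at 0.27 and Mir143 at 0.17. The pluripotency list was higher at 0.33 (percentile 98.7; 6 of 7 members). The let-7, neuronal, Dlk1-Dio3 and Hox cluster lists stayed inside the range of random lists, with medians of -0.0034, -0.080, -0.012 and -0.15. So did the hepatic and erythroid lists, with medians of -0.087 (percentile 36.4) and -0.25 (percentile 13.7).

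**Figure D3:**
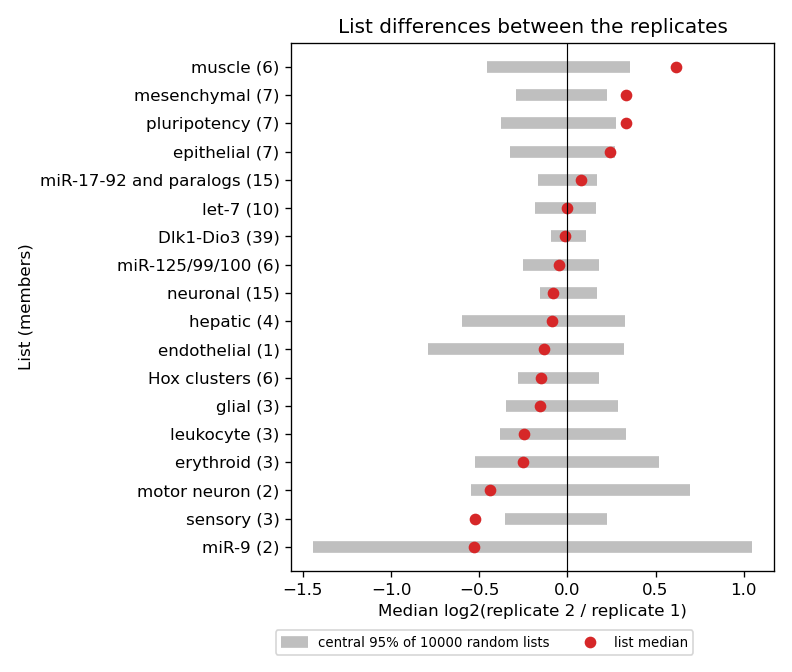
Median log2 ratio of replicate 2 to replicate 1 (x axis) of the members of each list (red points; member numbers in brackets), with the central 95% of 10000 random lists matched on mean expression (grey bars). The muscle, mesenchymal and pluripotency medians lie to the right of their bars and the sensory median, at -0.52, to the left.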

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

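The test of shared copies was chosen after the result was seen, and the strand test beforehand.

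The opposite-strand column, used only in alternative settings, held 100058 counts in replicate 1 and 85834 in replicate 2. Summed over both libraries, they fell mainly on Gm24321 (55630 counts), Gm25927 (41773), Gm25252 (31540), Gm24083 (21183), Gm25301 (16707) and Gm25750 (7017), predicted genes that had 0 to 2 same-strand counts. In M21 these genes are overlapped on the other strand by Mir409, Mirlet7e, Mir376a, Mir191, Mir378a and Mir380, which are not analysed here as genes of their own. Of all opposite-strand counts, 99.8% lay on the 32 genes with a miRNA gene on the other strand. A candidate explanation is that these counts are reads of well-known miRNAs that were annotated only as their antisense partner. Taken so, Mir409 would stand at 4332 ± 408 CPM (SD, n = 2) and Mirlet7e at 3277 ± 42.6 CPM, and no biological explanation was tested.

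A second signal outside the gene counts is the multimapping class, with 3921182 reads in replicate 1 and 3310889 in replicate 2. In 17 miRNA number families with both kinds of locus, loci that share 20 nt with another copy had the lower mean CPM in 12, or 70.6% of families (exact two-sided sign test p = 0.143). Let-7 loci that share sequence averaged 295 CPM and those that do not 15657 CPM, and miR-26 loci 8.40 and 10548 CPM. The exceptions were the miR-28, miR-302, miR-466, miR-669 and miR-7 families, but the loci of miR-466 and miR-669 that share no stretch were at 0 CPM, so these 2 families could not have gone the other way. Without them, a choice made after the values were seen, 12 of 15 families (80%) had the lower mean in the sharing loci (exact two-sided sign test p = 0.0352). Loss of shared reads and lower expression of these copies cannot be told apart by this test at any percentage, since both predict a lower mean in the sharing loci, and no biological explanation was tested.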

How the results depend on the processing

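The list shares with credited opposite-strand counts and the list differences of members with 100 counts summed were chosen after seeing the data. No called list difference changed direction, but without Mir10a, and with Mir99a kept, the order of the Hox cluster and miR-125/99/100 lists reversed. With a minimum of 1 count, 589 genes were detected in place of 371, and the 10 most abundant genes held 64.5% of the unstranded counts. Without Mir10a in the total, 14 list shares moved by more than the replicate SD: Hox clusters 21.6%, miR-125/99/100 22.9%, let-7 8.36%, Dlk1-Dio3 6.62%, miR-17-92 6.09%, endothelial 2.08%, mesenchymal 1.21%, neuronal 1.05%, glial 0.343%, epithelial 0.0927%, miR-9 0.0496%, pluripotency 0.0429%, leukocyte 0.0310% and motor neuron 0.0267%. The larger values follow from the smaller total. With unstranded counts the miR-125/99/100, neuronal and leukocyte shares were 17.9%, 0.827% and 0.0414%, and with opposite-strand counts credited to the overlapping gene 17.9%, 0.827% and 0.0414%, and Dlk1-Dio3 5.97%. The leukocyte share grew because opposite-strand counts on Mir142b are then included. Taking the largest locus of each family, the log2 ratios were -4.28 for miR-9 to neuronal, 0.45 for let-7 to miR-17-92 and 1.57 for neuronal to glial. The miR-9 list difference was 0.12 without its member of low counts (-0.53 with it). The muscle list difference left the outer 5% with unstranded counts (0.30), in which Mir1b has 5 opposite-strand reads in replicate 1. The muscle share, mostly from Mir206, was 0.0183% in replicate 1 alone and 0.0419% in replicate 2 alone. With 2 replicates, leaving 1 out always moves a mean by less than their SD, so this says nothing about stability. Depth limits genes under 10 counts, and multimapping may limit multi-copy miRNAs. No paired analysis was possible because there is a single group, with no other group to pair it with. The ratios between lists were taken within each library.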

Other observations

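Several further miRNA groups, listed after the values were seen, were abundant. The 6 miR-30 genes held 2.20% ± 0.12 (SD, n = 2) of the counts, the Mir130 and Mir301 genes 2.25% ± 0.17, the 6 miR-181 genes 1.96% ± 0.043, the miR-23/24/27 genes 1.41% ± 0.17 and the 3 miR-26 genes 1.06% ± 0.12. The X-linked genes around Mir322 held 0.873% ± 0.14 and the Mir15, Mir16 and Mir195 genes 0.376% ± 0.019. Where copies share sequence, reads may be missing, so these shares may be underestimates and do not rank the families. The 2 sharing miR-26 genes averaged 8.40 CPM, and the miR-26 share came almost entirely from Mir26b at 10548 CPM. The 4 sharing miR-181 genes averaged 1439 CPM and the other 2 averaged 6909 CPM. For miR-30, the 2 sharing genes averaged 32.0 CPM and the other 4 averaged 5479.5 CPM.

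The tests of counting error and normalization in the next lines were chosen after the result was seen, and the tests of list members and of neighbours beforehand. Mir449a and Mir1298 were higher in replicate 2. Counting error is argued against by the lower exact 95% bound of 5.79 on the ratio of Mir449a shares. The lowest log2 difference of Mir449a over 3 scalings was 2.63, but the scalings differed by 0.033 at most, too little to test normalization. A single scaling factor moves all genes alike, whereas 277 of 306 genes differed by less than 0.5 log2 units (SD 0.38). Mir449a at 2.63 and Mir1298 at 1.40 lie far outside that spread, which argues against a single scaling factor for these 2 genes. One hypothesis is that replicate 2 held more choroid plexus or ciliated cells, since Htr2c, the host gene of Mir1298, is a choroid plexus gene. Of the 11 listed genes, the 4 not looked at before and with at least 10 counts summed (Mir34b, Mir34c, Mir448 and Mir211) had a median log2 difference of 0.35 (percentile 95.01 of random lists), with Mir34c at 0.45, Mir448 at 0.44, Mir34b at 0.27 and Mir211 at -0.18. These 4 are not independent, which the percentile ignores: Mir448 lies in the same host gene, Htr2c, as Mir1298, and Mir34b and Mir34c lie close together on chromosome 9. The median lies between the 0.5 set for the hypothesis and the 0.2 set against it, so the test does not decide, and a difference in dissection stays open.

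A further hypothesis was that neighbouring miRNA genes, which often share a primary transcript, differ together between the replicates. The mean absolute gap in log2 difference over 97 same-strand neighbour pairs within 10 kb was 0.268, against 0.313 for partners matched on mean expression (one-sided permutation p = 0.0454). The gap was smaller among neighbours by a narrow margin, and its source was not tested. Pairs from the same cluster are not independent, which may make the p-value too small. For example, all 39 Dlk1-Dio3 and all 15 miR-17-92 members compared between the replicates lie within 10 kb of another member.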
